A study of Mus musculus with 3 samples.

How the data were processed

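Single-cell RNA was measured in 3 libraries of cells sorted from mouse suprarenal aorta, 1 library for each of 3 groups. Per the labels, the control pool held aortas of 5 C57BL/6 mice on chow. The room air pool held aortas of 5 Apoe-deficient mice on a Western diet for 16 weeks. The aneurysm pool held aortas of 4 Apoe-deficient mice that received the same diet for 16 weeks with cigarette smoke and developed a measurable dilatation. Cells positive for CD45 and negative for CD31, and cells negative for CD45 and positive for CD31, were sorted from each pool, so that the number of endothelial cells against leukocytes was set by the sort. A smoke group without aneurysm that the labels also count was not analysed here.

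The values deposited by the authors are counts, whole numbers of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization. The libraries were made with the 10x Genomics 3' v2 chemistry and processed with Cell Ranger and STAR on mm10, per the submitters' processing notes. The version of Cell Ranger is not given in the sources used here. The matrices list called barcodes only and hold 27998 genes. They hold 782 barcodes in control, 1851 in room air and 2842 in aneurysm, beside the 738, 1736 and 2685 cells that the labels state.

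Barcodes were kept with at least 200 genes and at most 10% of UMIs from mitochondrial genes, which left 778, 1848 and 2839. Doublets were scored with Scrublet in each library as provided in scanpy, at an expected rate of 0.8% per 1000 barcodes. Its automatic threshold marked 5 of 5465 cells (0.0915%) and was not used. The rule set for that case removed the cells with the highest scores up to the expected rate, which were 5 in control, 27 in room air and 64 in aneurysm. Kept were 773, 1821 and 2775 cells. Clusters 10 (neutrophil-like), 11 (macrophage-like with B and T cell genes) and 28 (B-cell-like with T cell genes) carried genes of another class and may hold doublets that the scores missed.

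Counts were scaled to 10000 UMIs per cell and log-transformed. The 3 libraries were clustered together without integration, from 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1, which gave 28 clusters. No deposited annotation of cell types was used. A cluster was called by a class name with the suffix -like from markers of 25 classes written before the data were examined, if at least 3 markers of the class were detected in at least 10% of its cells and its mean marker score was at least 0.6. That score limit was set after the clusters were seen. It left clusters 17 and 22 unnamed, with 66 control, 42 room air and 61 aneurysm cells in all, which were 8.54%, 2.31% and 2.20% of the kept cells. Cluster 17 was led by genes of cell division (Top2a, Birc5, Stmn1) and cluster 22 by Retnla, Lyz1 and Ear2.

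Clusters were defined by these leading genes. The macrophage-like class joined clusters 2 (Spp1, Gpnmb, Mmp12), 4 (C1qa, Adgre1, Ms4a7), 7 (Apoe, Ccl24, Pf4, Lyve1), 11 (C1qc, Cx3cr1), 12 (Ccl8, Cd209f, Folr2) and 23 (Ifit3, Cxcl10, Rsad2). The T-cell-like class joined clusters 5 (Dapl1, Cd8b1, Lef1), 6 (Izumo1r, Cd4), 8 (Gzmk, Nkg7, Cd8a) and 20 (Klra1, Klra6, Ccl5). The other classes were B-cell-like (1 and 28, Ms4a1, Cd79a), monocyte-like (9, Chil3, Hp, and 19, Treml4, Ace), cDC2-like (3, Cd209a, Ifitm1), cDC1-like (15, Xcr1, Naaa), mature-dendritic-cell-like (14, Ccr7, Fscn1), neutrophil-like (10, S100a8, Retnlg), gamma-delta-T-like (13, Cd163l1, Blk), NK-like (16, Ncr1, Klrb1c), ILC2-like (18, Calca, Gata3), plasma-cell-like (24, Jchain, Mzb1), pDC-like (26, Siglech, Ccr9), endothelial-like (25, Aqp1, Emcn) and fibroblast-like (27, Dcn, Col1a2). Among the 10 leading genes of clusters 7 and 12 there were 0 of the macrophage markers and 1 marker of another class each (Lyve1 and Clec10a). Both were kept as macrophage-like because they carried 7 and 4 genes when the macrophage lists were counted with the markers, and the macrophage class was also compared without them. Clusters 2, 20 and 23 also had 0 markers of their class among the 10 leading genes, and 0 of another class. Cluster 2 carried 7 genes when the lists were counted and clusters 20 and 23 carried 0, so the T-cell-like class was also compared without cluster 20 and the macrophage-like class without cluster 23. Cluster 21 (Cytl1, Clu) scored as endothelial but had 0 endothelial markers and 1 smooth muscle marker among its 10 leading genes, so it was compared by its number.

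UMIs were summed per library and class and expressed as CPM, the share of each gene in the UMIs of the class on the customary scale. The 2 comparisons were room air against control and aneurysm against room air, in each class with at least 25 cells in both libraries, which gave 17 comparisons over 11 classes or clusters. Ratios carry exact conditional binomial 95% intervals, shares carry exact Clopper-Pearson 95% intervals, and a level of 0 was compared against a floor of 3 counts over the class. All intervals and floors cover counting error only. With 1 library per group no test was run, and no difference could be set against a spread between replicates.

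The cell markers, 31 gene lists, comparisons, filters and rule for named genes were written before the data were examined. For each list, the median over its members with at least 20 UMIs in the higher library was taken of the log2 ratio of CPM with 10 CPM added to each side. It is given with a Poisson resampling interval (1000 draws) and with its percentile among 10000 random lists matched on mean expression in 20 bins, a description of these libraries. Of the marker and list genes, 12 were not found in the files under their symbols. Genes were named if they had at least 20 UMIs in the higher library and a 95% interval wholly beyond 1.5-fold. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor, predicted and sex-linked genes were left out. Of the genes that passed, the 12 highest and 12 lowest were named in macrophage-like cells and the 5 highest and 5 lowest in other classes, with up to 4 members of each list. Genes named after their values were seen are said to be so, and a few genes that met the rule are not reported here.

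Shares of cells with a UMI were taken after each cell was thinned to 1000 UMIs. No cell of the classes concerned was shallower, so none was left out. RNA free in the droplet suspension was measured by the level of 8 macrophage genes in B-cell-like cells. Free RNA of any gene was then taken as the library's mean CPM times the share of it that these 8 genes showed in B-cell-like cells. This definition replaced an earlier one, the lower of the B-cell and T-cell levels, after the data were seen, since that one also removed genes that every class expresses. In room air it lay below the level in B-cell-like cells for Cytl1, Mmp3, Slpi, Saa3, Jchain, Mgp, Ccl5 and Ifit3, and above it for Clu, Col3a1 and Mmp12.

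The rule was tested on simulated data with known ratios. Counts of both libraries were drawn with Poisson noise from the same room air profile. The simulation therefore covers counting error only, and not spread between cells or pools, cluster mixture or free RNA. Changed genes were drawn only from those with at least 50 expected UMIs in the library with fewer UMIs. The shares of changed genes named below do not cover genes with fewer, which the rule admits from 20 UMIs. In the aneurysm and room air setting, the 95% interval held the true ratio for 95.9% of 9985 genes, and 42 of 50 genes set 2-fold higher and 31 of 50 set 0.5-fold were named, with 3 of 9785 unchanged genes. In the room air and control setting it held the ratio for 95.7% of 9294 genes, and 42 and 36 of 50 were named, with 5 of 9094 unchanged genes.

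Alternatives written before the data were examined were stricter cell filters, doublets kept, another denominator, resolutions 0.5 and 2, clustering of each library on its own, classes from each cell's own markers, thinning to 1000 UMIs, other scalings, pseudocounts of 1 and 50 CPM, equal weight per cell or per macrophage cluster and no minimum of 20 UMIs. Added after the data were seen were free RNA subtracted, clusters formed without Apoe, cluster 22 counted as macrophage-like, and the classes without cluster 11, without cluster 20, without cluster 23, without cluster 28 and without clusters 7 and 12. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.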

Results

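The aortas of 14 mice gave 3 libraries, 1 for each group, so that no value below has a replicate. Control held 2568192 UMIs, room air 9998517 and aneurysm 16698309. The median barcode held 2681, 3884 and 4476 UMIs, and 1136, 1556 and 1640.5 genes. The lowest total of a listed barcode was 1082 UMIs in control, 1755 in room air and 1919 in aneurysm. The median share of mitochondrial UMIs was 2.75%, 2.17% and 2.43%, and the stated viability was 73%, 91% and 94%. Room air against control asks about loss of Apoe and the Western diet, which were given together. Aneurysm against room air asks about smoke exposure and the selection of mice with a dilatation, which also came together.

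The knocked-out gene Apoe, which encodes the ligand that clears remnant lipoproteins, had 10536 CPM over all control cells, 17.1 CPM in room air and 12.9 CPM in aneurysm. The remaining UMIs of Apoe in the deficient mice were 167 and 208. The female transcripts Xist and Tsix had 0 UMIs in each library, and the Y-linked genes were detected in each, with Ddx3y at 50.04, 52.1 and 50.7 CPM, Eif2s3y at 55.6, 63.6 and 76.7 CPM, Kdm5d at 7.09, 9.91 and 7.34 CPM and Uty at 14.6, 14.7 and 13.6 CPM. On mm10, Apoe (ENSMUSG00000002985) lies on chromosome 7 from 19696109 to 19699188, Spp1 (ENSMUSG00000029304) on chromosome 5 from 104435118 to 104441050, and Mmp12 (ENSMUSG00000049723) on chromosome 9 from 7344381 to 7369499. Lyve1 (ENSMUSG00000030787) lies on chromosome 7 from 110850607 to 110863239, Gpnmb (ENSMUSG00000029816) on chromosome 6 from 49036546 to 49070929, Trem2 (ENSMUSG00000023992) on chromosome 17 from 48346401 to 48354147 and Gzmk (ENSMUSG00000042385) on chromosome 13 from 113171608 to 113225908. All of these are annotated as protein-coding genes.

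Macrophage-like cells made up the largest leukocyte class of each library as the clusters were named, and their share was lower in each Apoe-deficient library than in control. They were 311 of 659 leukocyte-class cells in control (47.2%, 95% interval 43.3 to 51.1), 560 of 1735 in room air (32.3%, 30.1 to 34.5) and 673 of 2679 in aneurysm (25.1%, 23.5 to 26.8). Conventional type 2 dendritic cells (cDC2-like), which present antigen to CD4 T cells, were 0.455% of control leukocytes (3 cells), 7.95% in room air and 11.05% in aneurysm. Cluster 22, left unnamed, had 1 cDC2 marker (Cd209a) and 1 monocyte marker (Fn1) among its 10 leading genes. It held 43 control, 3 room air and 17 aneurysm cells, so the small control share of cDC2-like cells depends on leaving it out. Mature dendritic-cell-like cells, the migratory state that carries antigen to lymph nodes, were 2.36% in room air and 3.14% in aneurysm. They were 0 of 659 in control, with an exact upper bound of 0.558% and a floor of 3 counts at 0.455%. T-cell-like cells were 15.02%, 24.2% and 22.2% in control, room air and aneurysm.

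B-cell-like cells were 15.02% of control leukocytes, 13.03% in room air and 17.2% in aneurysm. Neutrophil-like cells were 1.21%, 4.78% and 3.84%, and gamma-delta-T-like cells, a source of interleukin 17 in tissues, were 0.607%, 3.80% and 2.20%. ILC2-like cells, innate lymphocytes of type 2 responses, were 4.86% in control, 1.44% in room air and 1.61% in aneurysm. Monocyte-like cells were 8.80%, 5.13% and 7.39%, cDC1-like cells were 3.79%, 2.19% and 2.16%, and NK-like cells were 2.88%, 1.21% and 2.72%. Mast cells and basophils formed no cluster in these libraries. Cells of cluster 21 (37, 26 and 14) and of the endothelial-like cluster 25 (10, 10 and 11) depend on the sort and were not compared as shares, and 1, 8 and 10 fibroblast-like cells were seen although the sort should remove them. The control share of macrophage-like cells was 31.3% with classes from each cell's own markers, and it was 6.20% without clusters 7 and 12, which held 0 macrophage markers among their 10 leading genes, below the 22.3% then found in aneurysm, so the lower share in the Apoe-deficient libraries, and the place of macrophage-like cells as the largest control class, rest on those clusters. In aneurysm T-cell-like cells outnumbered macrophage-like cells when clusters 7 and 12, or cluster 11, were left out.

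**Figure D1:**
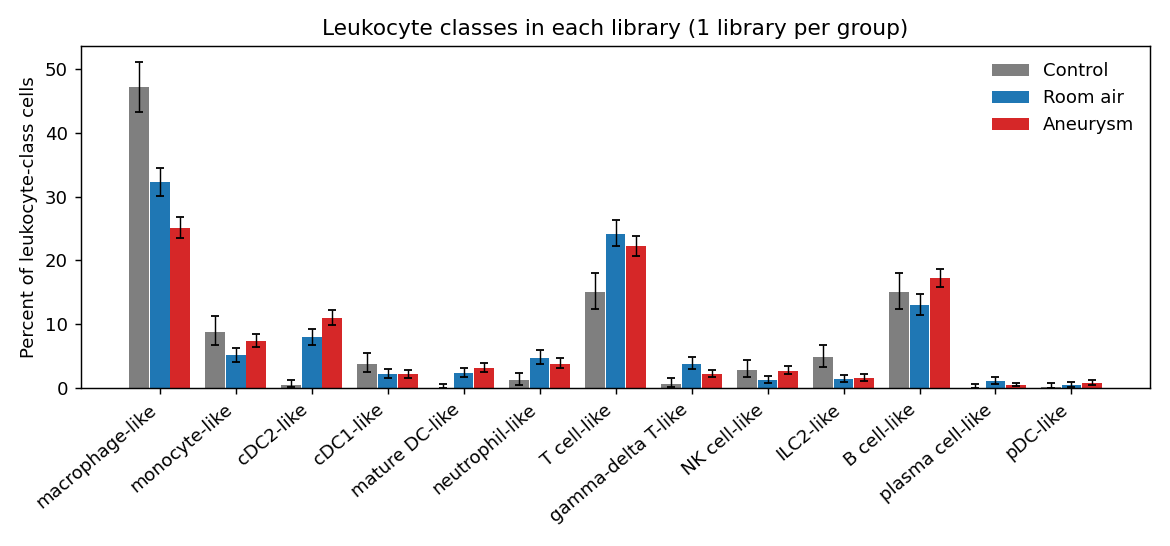
Each bar gives the percent of leukocyte-class cells (y axis) in 1 class (x axis) for the control, room air and aneurysm libraries, with exact 95% binomial intervals for counting error only. Macrophage-like cells stand at 47.2%, 32.3% and 25.1%, and cDC2-like cells at 0.455%, 7.95% and 11.05%.

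Within the macrophage-like and T-cell-like classes, the libraries held different clusters. Because the genes that lead a cluster also differed between libraries, the cells were clustered again without Apoe and the leading genes of clusters 2, 7 and 8, 30 genes in all, and the counterparts were counted. The counterpart of cluster 7, macrophage-like cells of the resident type, held 32.5% of all control cells (29.2 to 35.9), 0.494% in room air and 0.288% in aneurysm. The counterpart of cluster 2, macrophage-like cells of the lipid-associated type, held 0.129% in control, 11.04% in room air (9.63 to 12.6) and 10.5% in aneurysm (9.34 to 11.6). The counterpart of cluster 8, T-cell-like cells with Gzmk and Cd8a, held 0.259% in control, 12.9% in room air (11.3 to 14.5) and 3.24% in aneurysm (2.62 to 3.97). A cluster that comes mostly from 1 library may be a trait of that library.

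**Figure D2:**
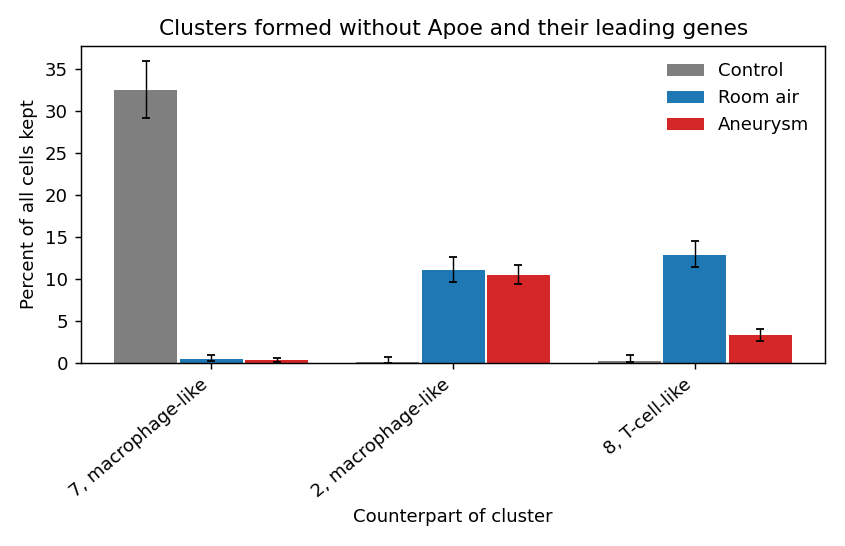
Each bar gives the percent of all kept cells (y axis) in the counterpart of clusters 7, 2 and 8 (x axis), formed without Apoe and their leading genes, for the 3 libraries, with exact 95% binomial intervals for counting error only. The counterpart of cluster 7 is at 32.5% in control against 0.494% and 0.288%, and that of cluster 8 at 12.9% in room air against 3.24% in aneurysm.

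In macrophage-like cells, genes of lipid-associated macrophages were higher in room air than in control and genes of resident macrophages were lower. Spp1, which encodes the secreted phosphoprotein osteopontin, had 7332 CPM in room air and 5.87 CPM in control, 1249-fold higher (606 to 3107). Gpnmb, a transmembrane glycoprotein of lipid-laden macrophages, had 365 CPM in room air and 0 in control, at least 145-fold higher. Fabp5, a carrier of fatty acids, was 63.6-fold higher (37.9 to 117) and Lgals3, which encodes galectin-3, was 8.51-fold higher (7.86 to 9.23). Lyve1, a receptor for hyaluronan on perivascular macrophages, was 19.8-fold lower (16.7 to 23.7), and Ccl24, a chemokine for eosinophils, was 18.1-fold lower (15.4 to 21.4).

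Other genes that were higher in room air included AA467197 (200-fold, 35.8 to 7921, from 1 control UMI), Il1rn, the antagonist of the interleukin 1 receptor (147-fold, 26.3 to 5823, from 1 control UMI), Syngr1 (40.1-fold, 13.6 to 195), Ly6a (20.2-fold) and Cd72 (8.65-fold). Jchain (at least 193-fold), Slpi (25.5-fold) and Ccl5 (11.9-fold) were also higher, but free RNA was put at 78.6%, 77.6% and 57.3% of their level in room air macrophage-like cells. Lower genes included Apoe (749-fold), Retnla, a marker of alternative activation (17.3-fold), the C-type lectins Cd209g (10.0-fold) and Cd209f (7.30-fold), Fcna (9.96-fold), Fxyd2 (9.73-fold), the haemoglobin scavenger receptor Cd163 (7.25-fold), Pf4 (6.92-fold), Ltc4s (6.90-fold) and the folate receptor Folr2 (6.79-fold). These ratios set 287 control cells of cluster 7, out of 311, against a room air class with 195 cells of cluster 2, 203 of cluster 4, 67 of cluster 11, 46 of cluster 12, 45 of cluster 23 and 4 of cluster 7.

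The lipid-associated list had a median log2 ratio of 1.60 (1.40 to 1.83), with 17 of 18 measured members higher, 16 of them over 1.5-fold. The exception was Cd36, a scavenger receptor for oxidised lipoproteins, which was 5.13-fold lower. The resident list had a median of -2.59 (-2.67 to -2.47), with 19 of 19 members lower. They lay at percentiles 100 and 0 of matched random lists. Clusters 7 (287 of 311 control cells) and 2 (195 of 560 room air cells) had 0 macrophage markers among their 10 leading genes. Both carried 7 genes of the macrophage lists there, so these percentiles and directions partly follow from how the class was drawn. The inflammatory cytokine and chemokine list had a median of 0.60 (0.35 to 0.78) with 11 of 16 members higher, among them the cytokine Il1b (4.62-fold), the chemokines Ccl4 (2.90-fold) and Ccl2 (2.55-fold), and Tnfaip3, an inhibitor of NF-kB signalling (3.44-fold). The extracellular protease list had a median of 1.09 (0.93 to 1.30), with Mmp12, the macrophage elastase, 7.88-fold higher (6.48 to 9.66), the membrane-bound Mmp14 15.6-fold higher, the collagen-degrading Ctsk at least 15.9-fold higher and the gelatinase Mmp9 5.59-fold lower (4.40 to 7.12). These medians stand beside a median of 0.11 over all 8576 genes.

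Lists of lipid handling and degradation were higher in room air as well. Of the LXR and cholesterol efflux genes 12 of 14 were higher (median 0.80), among them the sterol transporter Abcg1 (9.46-fold), the desaturase Scd2 (10.2-fold), Apoc4 (at least 12.9-fold) and Nr1h3, which encodes LXR alpha (5.27-fold). In the lysosome list 22 of 23 were higher (median 0.55), among them Ctsd (4.13-fold), Ctsz (3.01-fold) and Ctss (2.97-fold). Cholesterol synthesis had a median of -0.01, with 5 higher and 7 lower, and Mvd 3.37-fold higher and Insig1 1.68-fold lower. Scavenger and efferocytosis receptors went both ways (9 higher and 6 lower, median 0.48), with Cd300lf 9.54-fold higher, Cd5l at least 9.19-fold higher and the phosphatidylserine receptor Timd4 10.4-fold lower. The osteoclast and calcification list had a median of 0.58, with Acp5, the tartrate-resistant acid phosphatase, 10.1-fold higher.

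Interferon response genes were higher in 22 of 22 measured members (median 0.95, 0.85 to 1.14), among them the chemokines Cxcl10 (22.4-fold, 7.59 to 110) and Cxcl9 (at least 9.29-fold) and the antiviral genes Irf7 (4.65-fold) and Ifit1 (4.26-fold). Cluster 23, which is led by interferon genes, held 45 room air and 2 control cells of this class. Cxcl10 had 56.5 CPM in the room air class, but 8.02, 13.9, 25.7 and 8.38 CPM within its clusters 2, 4, 11 and 12. The size of its ratio therefore rests largely on cluster 23. The glycolysis and hypoxia list was higher in 16 of 18 (median 0.83, or 0.96 with genes at 0 set to their bound), with Pkm 3.20-fold and Pgk1 3.15-fold higher. MHC class II genes were higher in 10 of 11 (median 0.55, H2-Ab1 1.59-fold), and NRF2 antioxidant genes in 12 of 16 (median 0.36), with the glutathione reductase Gsr 4.18-fold and Pgd 2.29-fold higher. Protease inhibitors had a median of 0.68 (7 higher, 4 lower; 0.30 with free RNA subtracted), with Timp1 30.5-fold higher (5.35 to 1215) and Serpinf1 2.72-fold lower. The growth factor and matrix list had a median of 0.51, but 0.037 with free RNA subtracted, with Thbs1 49.3-fold higher (8.74 to 1960), Pdgfa 3.43-fold higher and Ecm1 1.92-fold lower. Complement genes had a median of -0.33 (5 higher, 7 lower), with C5ar1 2.03-fold lower and C3 7.47-fold higher. Aryl hydrocarbon receptor targets, 3 genes, had a median of -0.47, with Tiparp 2.17-fold lower. Oxidative phosphorylation (0.15), cell cycle (0.22) and dissociation stress (0.20) had medians near that of all genes, with Cycs 1.69-fold, Mcm6 1.90-fold and Dnaja1 2.99-fold higher and Jund 1.95-fold lower. With free RNA subtracted the medians were 0.33 for lysosome, 0.31 for scavenger receptors, 0.28 for MHC class II, 0.24 for NRF2, -0.069 for oxidative phosphorylation, -0.084 for cell cycle and -0.0018 for stress, beside -0.068 over all genes. The protease median was 0.31 when members with at least 1 UMI were counted, and the aryl hydrocarbon receptor median was then 0.04.

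**Figure D3:**
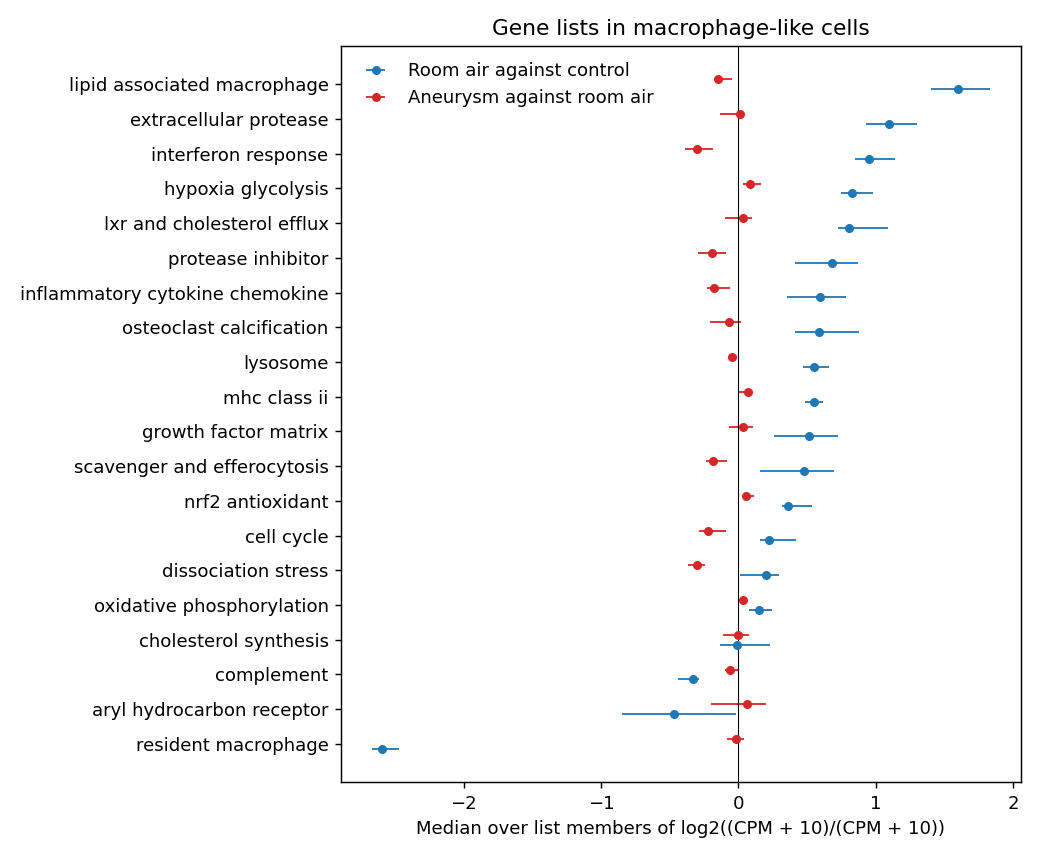
Points give the median over list members of the log2 ratio of CPM with 10 added to each side (x axis) for 20 gene lists (y axis) in macrophage-like cells, and lines give the 95% counting interval. Room air against control runs from -2.59 for the resident list to 1.60 for the lipid-associated list, and aneurysm against room air stays between -0.30 and 0.08.

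Macrophage-like cells of the aneurysm library differed less from those of room air, and 10 genes met the rule as higher. Cxcl3, a chemokine for neutrophils, was 8.78-fold higher in aneurysm (3.84 to 24.7; 12.8 against 1.46 CPM), and Clec4e, the receptor Mincle for mycobacterial and dead-cell ligands, was 2.05-fold higher (1.70 to 2.48). Mmp12 was 3.31-fold lower (3.09 to 3.55; 209 against 693 CPM). The interferon-induced Cxcl10 was 5.47-fold lower (4.09 to 7.43) and Ifit3 was 2.68-fold lower (2.27 to 3.17). Within cluster 2 Cxcl3 was 7.80-fold and Clec4e 2.37-fold higher, while Clec4e had ratios of 0.791 (0.442 to 1.41) in cluster 4, 1.25 (0.478 to 3.47) in cluster 11 and 0.975 (0.243 to 5.60) in cluster 12. Mmp12 was 3.61-fold lower within cluster 2, 5.13-fold within cluster 4, 3.05-fold within cluster 11 and 1.37-fold within cluster 12, the last with an interval that included 1 (0.631 to 2.79). Its room air levels in clusters 4, 11 and 12 were 123, 56.2 and 50.3 CPM, beside 67.6 CPM in B-cell-like cells. In aneurysm they were 23.9, 18.5 and 36.7 CPM, beside 5.19 CPM in B-cell-like cells. The lower ratios of clusters 11 and 12 therefore cannot be told from free RNA, and that of cluster 4 includes some of it. Cxcl10 was 2.09-fold lower within cluster 2 (0.865 to 5.27), 1.64-fold within cluster 4 (0.715 to 3.91) and 3.48-fold within cluster 11 (1.29 to 10.9), and had a ratio of 1.30 in cluster 12 (0.259 to 12.6). In clusters 2 and 4 it had 8.02 and 13.9 CPM in room air, where free RNA was put at 6.78 CPM. In aneurysm it had 3.83 and 8.48 CPM there, with free RNA put at 0.740 CPM, so those clusters give no direction. Ifit3 was 1.53-fold lower within cluster 2 (0.977 to 2.40), 2.85-fold within cluster 4 (1.64 to 5.14) and 1.45-fold within cluster 11 (0.833 to 2.54), and 1.95-fold higher within cluster 12 (0.914 to 4.77). Its room air levels in clusters 2, 4 and 11 were 24.6, 41.7 and 48.2 CPM. Room air B-cell-like cells had 41.6 CPM, and free RNA was put at 15.2 CPM.

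The other higher genes were Dppa3 (3.09-fold), Cdk5rap1 (3.36-fold), Tnip3, an inhibitor of NF-kB signalling (2.04-fold), the T cell transcription factor Tcf7 (2.18-fold), Dapl1 (2.19-fold), the lysosomal channel Mcoln3 (5.85-fold), and Nsg2 and Tmem108 (16.1-fold each, 2.60 to 664, from 22 UMIs against 1). Free RNA was put at 66.7% and 80.8% of the room air level for Tcf7 and Dapl1, and at over the whole of it for Nsg2 and Tmem108 (417% each). In aneurysm, where these genes were higher, it was put at 20.3%, 26.4%, 20.9% and 19.6% of their level. With it subtracted their log2 ratios were 1.06, 1.06, 0.39 and 0.39, beside 0.68, 0.65, 0.44 and 0.44 without subtraction. Free RNA at the estimated level therefore did not make these genes higher. Tcf7 and Dapl1 are also among the leading genes of T-cell-like clusters 5 and 6. The other lower genes were Jchain (5.52-fold), the calcification inhibitor Mgp (5.55-fold), Cytl1 (12.8-fold), Slpi (3.86-fold), Mmp3 (9.63-fold), Ccl5 (2.89-fold), Clu (6.10-fold), Col3a1 (9.80-fold) and Saa3 (3.32-fold). For these 9 genes free RNA was put at 49.2% to 89.1% of the room air level, against 10.5% for Mmp12, 12% for Cxcl10 and 14.9% for Ifit3. By the level in B-cell-like cells Ifit3 was at 40.8%, Clu at 24.5%, Cytl1 at 102% and Mmp3 at 92.3%, against 14.9%, 63.9%, 63.0% and 61.9% by the estimate. Chosen after their values were seen, as lower genes above this background, were the phospholipase Pla2g2d (2.76-fold), the interferon-induced Ifit3b (2.87-fold), Pam (2.87-fold), Slc15a2 (4.03-fold) and Siglech (4.85-fold). The room air class held the clusters given above, and the aneurysm class held 285 cells of cluster 2, 194 of cluster 4, 86 of cluster 11, 88 of cluster 12, 12 of cluster 23, which is led by interferon genes, and 8 of cluster 7.

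Of the 4 main lists, the lipid-associated list had a median of -0.15 (-0.18 to -0.05) with 11 of 18 members lower, among them Spp1 (1.33-fold, 1.31 to 1.35), Atp6v0d2 (1.33-fold) and lipoprotein lipase Lpl (1.22-fold). Spp1 was 1.47-fold, 1.93-fold and 2.35-fold lower within clusters 2, 11 and 12 and 1.49-fold higher within cluster 4. In clusters 11 and 12 it had 874 and 846 CPM in room air, where free RNA was put at 747 CPM. In aneurysm it had 453 and 359 CPM there, with free RNA put at 171 CPM, so the lower ratios of those clusters cannot be told from free RNA. The inflammatory list had a median of -0.18 (-0.23 to -0.06) with 13 of 18 lower, among them the cytokine Tnf (1.86-fold) and the chemokines Ccl12 (1.58-fold) and Ccl4 (1.31-fold), beside Cxcl3 above. The resident list had a median of -0.02 (-0.08 to 0.04), with Cd163 1.62-fold lower, and Cd209g 1.49-fold, Lyve1 1.48-fold and Cbr2 1.46-fold higher. Cluster 12, which is led by resident genes, held 8.21% of the room air class and 13.1% of the aneurysm class. The resident median was -0.28 with equal weight for each cluster of at least 20 cells in both libraries, which leaves out clusters 7 and 23. It was -0.32 without clusters 7 and 12. Cd163 was 2.99-fold, 2.37-fold, 2.68-fold and 2.18-fold lower within clusters 2, 4, 11 and 12. In cluster 2 it had 11.5 CPM in room air and 3.83 CPM in aneurysm, with free RNA put at 7.44 and 1.57 CPM. The protease list had a median of 0.01 (-0.13 to 0.04) and a mean of -0.17, with Mmp14 1.47-fold and the neutrophil collagenase Mmp8 2.30-fold higher. These medians lay at percentiles 0.01, 0, 30.9 and 60.3 of matched random lists. With each cell thinned to 1000 UMIs, which also gives each cell equal weight, the lipid-associated median was 0.0018 and the inflammatory median 0.04. Neither direction held in that setting. The lipid-associated median was -0.012 with the mean of each cell's CPM at full depth, so its change cannot be put down to depth. With free RNA subtracted the lipid-associated and inflammatory medians were -0.017 and -0.019, beside 0.13 over all genes, which was -0.014 without subtraction.

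Interferon response genes were lower in aneurysm in 19 of 22 (median -0.30, -0.39 to -0.19), with Rsad2 1.94-fold and Ifit1 1.89-fold lower. Without cluster 23, which is led by interferon genes and held 45 room air and 12 aneurysm cells, the median was 0.12, so the direction rests on that cluster, and the log2 ratios of Cxcl10 and Ifit3 were -0.47 and -0.33. With equal weight for each macrophage cluster, which leaves it out, the median was 0.14. Dissociation stress genes, the heat shock and early response genes that tissue digestion induces, were lower in 18 of 20 (median -0.30), with the chaperones Dnaja1 2.28-fold, Dnajb1 2.14-fold, Hspa1a 2.04-fold and Hspa8 1.55-fold lower. NRF2 antioxidant genes were higher in 12 of 16 (median 0.05), with Srxn1 1.66-fold, Slc7a11 1.39-fold and Gclm 1.35-fold higher and Cat 1.40-fold lower. Aryl hydrocarbon receptor targets, which tobacco smoke can induce, had a median of 0.06 over 3 genes, with Tiparp 1.06-fold higher (0.798 to 1.42).

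The remaining macrophage lists had small medians. Protease inhibitors had a median of -0.19 (2 higher, 9 lower), with Timp3 17.8-fold lower (4.45 to 155), Serpinf1 1.98-fold lower and Spint1 1.73-fold higher. Scavenger receptors had -0.19 (4 higher, 11 lower), with Mfge8, a bridge to dying cells, 2.21-fold lower and Cd300lf 1.32-fold higher. Cell cycle genes had -0.22 (2 higher, 14 lower), with Hmgb2 1.31-fold lower. The lysosome list had -0.05 (Atp6v0c 2.49-fold lower), complement -0.06 (Serping1 6.99-fold lower, Cfp 1.27-fold higher) and osteoclast genes -0.07. Medians were 0.03 for LXR and cholesterol efflux (Nr1h3 1.58-fold and Pltp 1.21-fold higher), -0.01 for cholesterol synthesis, 0.07 for MHC class II (Cd74 1.11-fold higher, H2-DMb2 1.40-fold lower), 0.08 for glycolysis (Slc16a3 1.39-fold higher, Pgk1 1.52-fold lower), and 0.03 for oxidative phosphorylation (Cycs 1.17-fold higher). The growth factor and matrix list had a median of 0.03 and a mean of -0.14, with Ecm1 1.67-fold higher, and Sparc 4.01-fold and Eln 7.18-fold lower. Free RNA was put at 62.9% of the room air level of Timp3, 57.2% of Serping1, 52.4% of H2-DMb2, 81.4% of Sparc and 130% of Eln, and with it subtracted their log2 ratios were -0.30, -0.47, 0.035, -0.10 and 0.059. The medians were then 0.016 for protease inhibitors, -0.054 for scavenger receptors, 0.14 for cell cycle, 0.099 for lysosome, 0.093 for complement, -0.079 for interferon and -0.11 for stress genes, beside 0.13 over all genes, and Hmgb2 had 0.032.

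Counted per cell at 1000 UMIs, Spp1 was seen in 0.643% of control macrophage-like cells, 65.0% in room air and 37.7% in aneurysm, against 0%, 54.0% and 14.8% of B-cell-like cells, so that most of the room air share lay at the level of free RNA. Without thinning the macrophage shares were 2.25%, 98.0% and 81.6%. Gpnmb was seen in 0%, 12.5% and 14.9% (B-cell-like 0%, 2.21% and 1.08%, unthinned 0%, 36.2% and 34.3%). The lipid receptor Trem2 was seen in 16.1%, 40% and 32.5% (B-cell-like 1.01%, 7.52% and 2.82%, unthinned 41.2%, 82.3% and 74.9%). Lyve1 was seen in 45.3%, 3.75% and 5.50% (B-cell-like 1.01%, 0.442% and 0.217%), and 73.3%, 13.4% and 15.6% unthinned. The median depth was 3275, 6267.5 and 7454 UMIs in macrophage-like cells and 1295, 2227.5 and 2398 in B-cell-like cells.

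Free RNA differed between libraries. The macrophage complement gene C1qa had 209 CPM in B-cell-like cells of control, 551 in room air and 163 in aneurysm, which was 3.03%, 11.4% and 3.58% of its level in macrophage-like cells. Over 8 macrophage genes the B-cell level was 2.88%, 11.6% and 3.67% of the macrophage level in the median. Spp1, Jchain, Slpi, Saa3 and Mgp were for this reason among the most different genes in classes that do not make them, and are not described there.

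**Figure D4:**
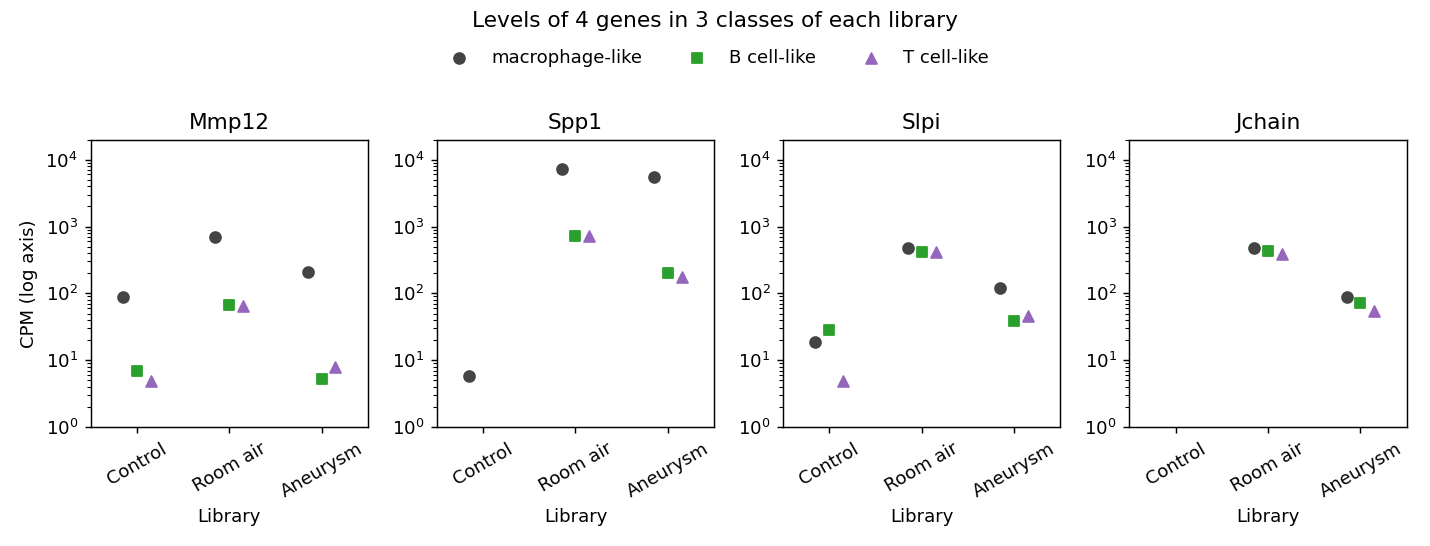
Points give the level of Mmp12, Spp1, Slpi and Jchain in CPM (y axis, log scale) in macrophage-like, B-cell-like and T-cell-like cells of each library (x axis), 1 value per class and library without error bars, and levels of 0 are not drawn. Mmp12 stands at 693 CPM in room air macrophage-like cells and 67.6 CPM in B-cell-like cells, while Jchain stands at 484 and 426 CPM.

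In T-cell-like cells, genes of cytotoxic effector cells were lower in aneurysm than in room air and genes of naive and memory cells were higher. Gzmk, a granzyme of effector-memory CD8 T cells, was 4.95-fold lower (3.95 to 6.26), Gzma, another granzyme, 7.84-fold lower (5.95 to 10.5), the chemokine Ccl5 2.91-fold lower and the tissue-homing receptor Cxcr6 2.11-fold lower. Igfbp4, a binding protein of insulin-like growth factors, was 4.77-fold higher (3.76 to 6.12), and the naive T cell regulators Satb1 and Tcf7 1.89-fold and 1.81-fold higher. The effector list was lower in 15 of 15 (median -0.84, -0.98 to -0.71), the naive and memory list higher in 8 of 10 (0.66, 0.57 to 0.84), and the checkpoint list lower in 5 of 5 (-0.53), with Pdcd1, which encodes PD-1, 2.33-fold lower. Cluster 8 held 221 of 420 room air cells and 76 of 596 aneurysm cells of this class, cluster 5 held 74 and 255, cluster 6 held 101 and 205, and cluster 20 held 24 and 60.

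The regulatory list in T-cell-like cells had a median of -0.18 (2 higher, 6 lower), the stress list -0.75 (1 higher, 15 lower; -0.12 with free RNA subtracted, beside 0.074 over all genes), the interferon list -0.48 (1 higher, 15 lower; Ifit1 3.04-fold and Isg15 2.21-fold lower) and the cell cycle list 0.02. Of the type 17 list 2 genes were measured, which gives no median, and both lay at the level of free RNA. Also higher were Sh3bp5 (3.05-fold), Dph5 (2.90-fold) and the receptor Klra7 (2.505-fold), which had a log2 ratio of 0.035 without cluster 20. At 1000 UMIs per cell, Gzmk was seen in 2.02% of control, 20.7% of room air and 3.69% of aneurysm T-cell-like cells (B-cell-like 0%, 2.21% and 0%, unthinned 2.02%, 37.1% and 7.55%), with median depths of 1895, 2498.5 and 2716 UMIs.

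Room air against control gave the reverse in T-cell-like cells. Gzmk was 11.5-fold higher in room air (4.88 to 35.7), Ccl5 4.56-fold, Cxcr6 4.29-fold, Pdcd1 at least 7.15-fold and the serpin Serpina3g at least 8.17-fold higher. Ccr7, the receptor for lymph node entry, was 2.84-fold lower, the quiescence factor Klf2 2.39-fold, S1pr1, the receptor for lymph node exit, 2.81-fold, Igfbp4 3.06-fold and Dapl1 3.10-fold lower. The effector list was higher in 15 of 15 (median 1.53, 1.51 at the bound), the checkpoint list in 5 of 5 (1.37), the regulatory list in 6 of 7 (1.26; Tnfrsf4 13.3-fold, 2.32 to 534), the interferon list in 15 of 15 (1.08, 0.90 at the bound) and the stress list in 14 of 16 (0.96; 0.28 with free RNA subtracted), and the naive and memory list was lower in 10 of 10 (-0.59). Foxp3, of the regulatory list, was seen at 1000 UMIs per cell in 0 of 99 control and 1 of 420 room air cells (unthinned 1.01% and 1.67%). The cell cycle list had 0.17. The median over all genes was 0.37 in this comparison, and the control class held 99 cells, 44 of cluster 5, 46 of cluster 6, 7 of cluster 20 and 2 of cluster 8.

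In B-cell-like cells the stress list was lower in aneurysm than in room air. Hps3, of the biogenesis of lysosome-related organelles, was 4.00-fold higher (1.73 to 11.4) and Zcwpw1 10.7-fold higher (1.75 to 440, from 25 UMIs against 1). The B cell activation list had a median of 0.05 (7 higher, 5 lower), the stress list -0.92 (2 higher, 15 lower), with Dnaja1 3.07-fold and Dnajb1 3.24-fold lower, the interferon list -0.30 (2 higher, 8 lower) and the cell cycle list -0.34 (1 higher, 8 lower). With free RNA subtracted the last 3 medians were -0.64, 0.065 and -0.11, beside 0.13 over all genes. Against control, room air B-cell-like cells had the activation marker Cd83 2.80-fold higher (1.68 to 5.00), the B cell precursor gene Vpreb3 6.57-fold lower (4.81 to 9.02) and the phosphatase Dusp2 5.44-fold lower. Their activation list had a median of 0.58 (8 higher, 3 lower), stress 0.93, interferon 0.51 and cell cycle 0.72, beside 0.14 over all genes. With free RNA subtracted these were 0.23, 0.26, 0.083 and 0.48, beside -0.088 over all genes.

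The interferon list was higher in aneurysm than in room air in cDC2-like, monocyte-like and mature dendritic-cell-like cells. In cDC2-like cells Ccl17, a chemokine for type 2 and regulatory T cells, was 9.90-fold higher (6.82 to 14.9) and Cxcl3 34.3-fold higher (5.97 to 1373, from 1 UMI in room air), and Fam129b was 2.83-fold higher. Cxcl3 had a log2 ratio of -0.06 when each library was clustered on its own, so its direction there depended on how the class was drawn. Interferon genes were higher in 14 of 18 in cDC2-like cells (median 0.36, 0.15 to 0.46; Irf7 1.98-fold higher, Ifit1 2.41-fold lower), in 13 of 17 in monocyte-like cells (0.24, 0.06 to 0.46) and in 10 of 10 in mature dendritic-cell-like cells (0.47, 0.10 to 0.74; Isg15 2.97-fold higher). In monocyte-like cells Retnla was 4.28-fold higher (3.06 to 6.16), Dmkn 5.36-fold, Rgl1 7.44-fold (2.43 to 37.0) and the growth factor Nrg1 13.1-fold higher (2.21 to 531, from 1 UMI in room air), the last with a log2 ratio of -0.08 at 1000 UMIs per cell. In mature dendritic-cell-like cells the lysozyme Lyz1 was at least 20.3-fold higher. The interferon list of mature dendritic-cell-like cells had a median of -0.25 with classes from each cell's own markers.

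In cDC1-like cells, which present antigen to CD8 T cells, Rinl was 5.33-fold and Fdps, of cholesterol synthesis, 2.72-fold higher in aneurysm, with list medians of -0.51 for stress, 0.26 for interferon and 0.01 for cell cycle. Stress and cell cycle medians were -0.18 and -0.20 in monocyte-like cells, -0.47 and -0.32 in cDC2-like cells, and -0.32 and -0.06 in mature dendritic-cell-like cells. The stress median was below 0 in each of the 10 classes compared between aneurysm and room air, but it was 0.11 in mature dendritic-cell-like cells with free RNA subtracted, beside 0.19 over all genes. Against control, room air cDC1-like cells had the antiviral regulator Irf7 7.21-fold higher (2.34 to 36.0) and Gzma 30.6-fold lower (12.4 to 97.6), with medians of 1.34 for interferon (7 of 7 higher), 0.72 for stress and 0.60 for cell cycle (-0.90 with classes from each cell's own markers), beside 0.26 over all genes. Room air monocyte-like cells had the chemokine Cxcl16 17.8-fold higher (4.78 to 149, with free RNA put at 44.2% of its level) and Lyz1 4.31-fold lower, with medians of 0.10 for stress, -0.09 for interferon and 0.14 for cell cycle, beside 0.19 over all genes.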

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

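The tests of dilution, of free RNA and of variation between pools were chosen only after the results were seen, while those at 1000 UMIs per cell were set before. Plasma-cell-like cells (cluster 24) made up 1.10% of room air cells (20 cells). In control 0 of 773 cells were seen, with an exact upper bound of 0.476% and a floor of 3 counts at 0.388%. Cells of the pDC-like class (cluster 26) made up 0.793% of aneurysm cells (22 cells), above the upper bound of 0.719% for control, where 1 was seen, but the aneurysm interval (0.497 to 1.20) overlaps that of control. Neither class entered a comparison of genes.

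The cells of cluster 8, with Gzmk and Cd8a, were fewer in aneurysm than in room air. Dilution by B cells and naive T cells was argued against, since cluster 8 cells per macrophage-like cell were at 0.286 of the room air ratio (0.212 to 0.377), where dilution needs 1. The share of T-cell-like cells with a Gzmk UMI at 1000 UMIs per cell was at 0.178 of that in room air (0.103 to 0.279). Lower depth in aneurysm was argued against by depth itself, since its T-cell-like cells were deeper (median 2716 against 2498.5 UMIs). Thinning could therefore not have come out for depth. The share does not use the border of cluster 8 within the class. Gzmk leads that cluster and the class was drawn by clusters, so the borders of the class were not tested. Variation between pools of mice cannot be told apart from the groups, because there was 1 library per group. Smoke exposure and dilatation may be biological explanations and were not tested apart from each other.

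Mmp12 and 11 other genes were lower in macrophage-like cells of aneurysm than of room air. For Mmp12, free RNA was argued against by a ratio of 0.326 (0.303 to 0.350) after its subtraction. For the other 11 genes the difference in CPM above B-cell-like cells, room air minus aneurysm, was taken. Its interval lay above 0 for 5 of them (Mgp, Ccl5, Clu, Cxcl10 and Ifit3). For the other 6 (Jchain, Cytl1, Slpi, Mmp3, Col3a1 and Saa3) that interval included 0, so free RNA stays a candidate explanation for them. For the 5 genes, free RNA as the whole cause is argued against only if it has the same CPM in macrophage-like and B-cell-like cells, which was not tested. Mgp and Ccl5 were also lower in aneurysm B-cell-like cells (6.68 against 58.9 and 84.6 against 442 CPM). Cxcl10 and Ifit3 are among the leading genes of cluster 23, which held 45 room air and 12 aneurysm cells. Variation between the pools, 1 library per group, cannot be told apart from smoke exposure and dilatation, which stay open and untested.

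The lipid-associated list was higher and the resident list lower in macrophage-like cells of room air than of control, a gap of 4.19 on the log2 scale. The gap was 3.91 with each cell thinned to 1000 UMIs. Thinning keeps the expected share of each gene in a cell, so it could hardly shrink a gap in CPM. Lower depth of the control library was therefore not decided by it. With free RNA subtracted the gap was 4.23, so free RNA at the estimated level was too little to make it. The 8 macrophage genes in B-cell-like cells stood at 11.6% of the macrophage level in room air and 2.88% in control. Subtraction of that size could not close such a gap, so it does not test whether the estimate is right. Variation between pools of mice cannot be told apart from the groups, with 1 library per group. Loss of Apoe and the Western diet may both be biological explanations, and neither was tested apart from the other.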

How the results depend on the processing

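The subtraction of free RNA, the counting of cluster 22 as macrophage-like and the classes without cluster 11, without cluster 20, without cluster 23 and without clusters 7 and 12 were chosen only after the data were seen, and the other alternatives below were set before. No paired analysis was possible because each group had 1 library. Across the alternatives, 7776 gene ratios stayed within their interval, 1241 moved and 30 changed sign. Of the medians of the 4 main macrophage lists 107 stayed, 42 moved and 3 changed sign, of other list medians 1207, 186 and 18 did so, and of macrophage shares 27 stayed and 9 moved. Of other shares 296 stayed and 46 moved. Equal weight per cluster and the class without clusters 7 and 12 gave no value for room air against control, where control held too few cells. Values are log2 ratios or medians unless given in percent, for macrophage-like cells unless another class is named, with AvR for aneurysm against room air and RvC for room air against control. Median-of-ratios scaling moved the median over all genes from 0.06 to 0.41 in RvC ILC2-like cells, from 0.26 to 0.37 in RvC cDC1-like cells, from 0.02 to 0.13 in RvC cluster 21 and from -0.10 to 0.02 in AvR T-cell-like cells, and totals without mitochondrial and ribosomal protein genes moved it from 0.37 to 0.13 in RvC T-cell-like cells, to -0.14 in RvC ILC2-like cells and to 0.05 in AvR T-cell-like cells. The lower depth of control limits ratios against it, and the cause of the changes below was not tested unless the setting itself shows it.

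Subtraction of free RNA moved the median over all genes as well, in AvR to 0.13 in macrophage-like, 0.13 in B-cell-like, 0.074 in T-cell-like, 0.22 in monocyte-like, 0.18 in cDC2-like, 0.29 in cDC1-like and 0.19 in mature dendritic-cell-like cells, and in RvC to -0.068 in macrophage-like cells, so the changes below include that common shift. With free RNA subtracted, AvR medians were 0.14 for proteases, -0.019 for inflammatory, -0.017 for lipid-associated and 0.12 for resident genes, and RvC resident was -2.74. Signs changed in AvR for Eln (0.060), Saa3 (0.16), cell cycle (0.14), complement (0.093), lysosome (0.099) and protease inhibitors (0.016), and in RvC for cell cycle (-0.084), stress (-0.0018) and oxidative phosphorylation (-0.069). They also changed for AvR Slpi (0.15) and stress (0.11) in mature dendritic-cell-like cells, Spp1 in cDC1-like cells (AvR 0.70, RvC -1.98), AvR Spp1 in cDC2-like cells (2.08), Tmem176a (AvR 0.47, RvC -0.28) and AvR Tmem176b (1.27) in T-cell-like cells, AvR cell cycle in monocyte-like cells (0.076) and AvR interferon in B-cell-like cells (0.065).

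With classes from each cell's own markers, macrophage shares were 31.3%, 23.1% and 19.0% in control, room air and aneurysm. Proteases were 0.088 in AvR and 0.62 in RvC, AvR inflammatory was -0.29 and AvR resident 0.087. Signs changed in AvR for the lipid-associated list (0.029), lysosome (0.010) and Mfge8 (0.068), for Arg1 in neutrophil-like (-0.79) and Ccl1 in T-cell-like cells (-0.17), for Cd74 (-0.45), Cpa3 (0.59) and H2-Eb1 (-0.10) in ILC2-like cells, and for Isg15 (-0.23) and interferon (-0.25) in mature dendritic-cell-like cells, and in RvC for Tubb5 (-0.25) and cell cycle (-0.90) in cDC1-like cells.

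With each library clustered on its own, the RvC medians were 0.85 for proteases, 1.40 for lipid-associated and -2.73 for resident genes, AvR lipid-associated was -0.18 and the control macrophage share 37.3%. Signs changed for AvR Arg1 in neutrophil-like cells (-0.49), RvC Col3a1 (-0.037), AvR Cxcl3 in cDC2-like cells (-0.060), and RvC Tubb5 (-1.20) and cell cycle (-1.22) in cDC1-like cells.

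With each cell thinned to 1000 UMIs, AvR proteases were 0.055, AvR resident -0.14 and RvC resident -2.40, and signs changed for AvR inflammatory (0.044) and lipid-associated genes (0.0018), Arg1 in neutrophil-like (-1.14), Cd74 in ILC2-like (-0.045) and Nrg1 in monocyte-like cells (-0.079). Equal weight per macrophage cluster took only clusters with at least 20 cells in both libraries, which left out clusters 7 and 23. With it, AvR inflammatory was -0.0082 and resident -0.28, and signs changed for Ccl12 (0.0077), Ifit1 (0.10), Ifit3b (0.15), interferon (0.14) and NRF2 genes (-0.0021). With the mean of each cell's CPM, RvC proteases were 0.71, lipid-associated 1.39 and resident -2.33, AvR lipid-associated -0.012 and resident -0.16, and AvR Cd74 in ILC2-like cells changed sign (-0.026).

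With members of at least 1 UMI, RvC proteases were 0.31 and RvC aryl hydrocarbon receptor genes changed sign (0.042). A pseudocount of 1 CPM gave RvC medians of 0.90 for inflammatory, 1.89 for lipid-associated and -2.71 for resident genes, and 50 CPM gave 0.24, 1.24 and -2.17, with 0.65 for proteases. At resolution 2 RvC proteases were 0.82 and resident -2.83, with doublets kept 0.93 and -2.73, and with cluster 22 as macrophage-like 0.70 and -2.38. With at least 500 genes and at most 5% mitochondrial UMIs, RvC resident was -2.71. Of all kept cells, 40.2% of control were macrophage-like. Without cluster 23, AvR lipid-associated was -0.18 and AvR inflammatory -0.010, and signs changed for AvR interferon (0.12), Ccl12 (0.034) and Ifit1 (0.080). Without cluster 20 no sign changed in T-cell-like cells. Without cluster 11 the macrophage share was 29.6% in room air and 22.6% in aneurysm. Without clusters 7 and 12 it was 6.20% in control and 22.3% in aneurysm, AvR proteases were -0.14 and AvR resident -0.32.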

Other observations

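Neutrophil-like cells (cluster 10) had Cxcl3 12.1-fold higher in aneurysm than in room air (3.97 to 60.5), Dmkn 14.2-fold higher (3.72 to 120), the arginase Arg1 8.68-fold higher (2.20 to 74.9), and the monocyte antigen Ly6c2 2.83-fold higher (2.06 to 3.96), while Ccl17 was at least 35.7-fold lower. This cluster mixed the macrophage gene C1qa (3801 CPM in room air, 3194 in aneurysm) with the neutrophil gene S100a8 (6842 and 5779 CPM), so its values cover more than 1 cell type, and Arg1 had a log2 ratio of -1.14 at 1000 UMIs per cell. Its list medians were -0.38 for stress, -0.02 for interferon and -0.10 for cell cycle. Gamma-delta-T-like cells had the chromatin remodeller Chd7 10.5-fold higher in aneurysm (2.54 to 92.4), Crot 4.94-fold, Avpi1 4.07-fold and Asb2 3.43-fold higher, and Klf2 4.70-fold lower (2.56 to 9.30). Their medians were -0.48 for stress, 0.88 for interferon (3 of 3 higher) and -0.54 for cell cycle.

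ILC2-like cells had Calca, the precursor of calcitonin gene-related peptide, at least 18.3-fold higher in room air than in control and 2.08-fold higher in aneurysm than in room air (1.56 to 2.81). The cyclic AMP-responsive Crem was at least 12.9-fold higher in room air than in control and Nrgn at least 8.10-fold lower. The mast cell protease Cpa3 was 78.5-fold lower in aneurysm than in room air (13.2 to 3185), as were Cd63 (5.45-fold) and Cebpb (5.00-fold), in a class of 25 room air and 43 aneurysm cells, but Cpa3 had a log2 ratio of 0.59 with classes from each cell's own markers. The stress and cell cycle medians were -0.53 and 0.19 for aneurysm against room air, and 0.53 and 0.38 for room air against control. In cluster 21, which carries endothelial and smooth muscle genes (26 room air and 37 control cells), genes of endothelial to mesenchymal transition were higher in room air in 8 of 9 (median 1.47, 0.85 to 2.38), with the contractile genes Acta2 5.93-fold (4.23 to 8.51) and Tagln 5.21-fold higher and Col3a1 6.07-fold higher. Lrg1 was at least 19.6-fold and the transcription factor Sox4 at least 8.10-fold higher, while Klk10 was 9.09-fold and the prostacyclin synthase Ptgis 5.79-fold lower. The adhesion list had a median of -0.12 (Icam2 2.84-fold lower), the shear-responsive list -0.25 (Thbd 2.43-fold lower, Edn1 2.15-fold higher), the arterial and venous list 0.58 (Gja4 2.19-fold and Vwf 1.64-fold higher) and the stress list 0.11.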
